A study of Mus musculus with 12 samples.

How the data were processed

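Gene expression was measured in mouse cells of the C57BL/6 strain in which ZNF335 (Zfp335 in the mouse), a zinc finger protein, had been knocked down on embryonic day 14.5, and in cells given a control knockdown, per the labels. The series design names short hairpin RNA and fluorescence-activated sorting, while the sample titles name small interfering RNA. The 12 samples formed 4 groups of 3: knockdown and control at a short term time point (1 day) and a long term time point (5 days). Total RNA was labelled with biotin for Affymetrix 3 prime expression arrays, per the labels' protocols. Groups followed the sample titles and source names, and time points the time label. The labels disagreed in 2 places. The description field of the 6 long term samples named the opposite group to their titles and source names, while the array codes in the instrument files went with the titles. Every sample also carried embryonic day 15.5 as its stage and postnatal day 0 as its harvest, so neither told the time points apart.

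The deposited table held 1 intensity per probe set and array for 45101 probe sets, on a linear scale as far as the values show. The step from probes to probe sets, any background correction and any scaling are not given in the sources used here. The column medians were 85.5, 123 and 95.6 in the short term controls, 85.1, 123 and 124 in the short term knockdowns, 147, 101 and 94.8 in the long term controls and 103, 145 and 117 in the long term knockdowns. Means trimmed by 2% ran from 186 to 239 in the short term arrays and from 451 to 529 in the long term arrays, so the table had not been brought to equal levels. It was therefore quantile normalized over the 12 arrays, 16 was added and log2 was taken. A fold change is thus on the log2(value + 16) scale, which understates changes of dim probe sets. The instrument files gave chip lot, fluidics station and scanner, and no expression values. Of these only the scanner entered a fit as a batch. The short term arrays shared a chip lot that no long term array had. No more than 0.397% of probe sets had identical values in any pair of arrays.

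The 64 control probe sets were left out and the upper 60% of the others by mean over all arrays were kept, 27022 probe sets. Of all probe sets, 34945 had 1 gene symbol (18193 genes), 932 had several and 9160 had none in the platform annotation, and 34754 of those with 1 symbol were brought to current symbols through their Entrez ID. No gene was named from a probe set with several symbols. Of the kept probe sets, 22044 had 1 symbol, for 12263 genes. Genome coordinates were not used here, since no source named a build.

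Group means were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, all 12 arrays in 1 fit with 8 residual degrees of freedom and no covariate. The contrasts were knockdown minus control at each time point, the difference of these effects, and long term control minus short term control. Benjamini-Hochberg adjustment ran over the kept probe sets with a threshold of 0.05. Single values were also compared by exact two-sided permutation, where 3 against 3 cannot go below p = 0.1. The number of arrays limits the precision. Nothing in the labels says that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

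The design, the alternatives and 28 gene lists were fixed before the data were examined. The lists covered apical progenitors (radial glia), intermediate progenitors and newborn neurons, postmitotic neurons, upper-layer and deep-layer projection neurons, DNA replication and G1/S, G2/M and mitosis, and microcephaly genes. They also covered REST/NRSF and its corepressors, neuronal genes with REST-binding RE1 sites, the trithorax H3K4 methyltransferase complex, p53 target genes, and Notch and Wnt pathway components. Others held axon growth and guidance, synaptic transmission, cytosolic ribosomal proteins, the mitochondrial respiratory chain, the type I interferon response, immediate-early and dissociation stress genes and RNA interference machinery. Markers of other cells covered microglia, endothelium and pericytes, erythroid cells, inhibitory interneurons, Cajal-Retzius cells, oligodendrocyte precursors, astrocytes, and meninges and fibroblasts. Lists were tested with limma's camera at a preset correlation of 0.01 between genes on the brightest kept probe set of each gene, adjusted over the 27 lists with at least 5 measured members; the erythroid list had 4. Camera compares a list with the other genes. An estimated correlation and fry were alternatives.

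The genes named were chosen by a rule: up to 12 each way for the knockdown comparisons and up to 5 each way for the other comparisons, of the largest log2 fold change among genes past the threshold whose group values did not overlap. Where fewer passed, the list was filled with non-overlapping genes of the smallest unadjusted p and a log2 fold change of at least 0.58 in size. For the difference of the effects, non-overlap was not required. Zfp335, Rest and up to 4 members of each list with the smallest p were added. The rule also allowed genes withheld from the text to be skipped, and none was.

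Both steps were tested on simulated data with the spread of these arrays. Over 5 runs on 27022 probe sets, limma recovered 3.2% of probe sets made to differ 2-fold in the short term comparison and 3.2% in the long term comparison. At 4-fold it recovered 46.4% and 47.6%, at 8-fold 79.2% and 79.2%, and at 16-fold 89.6% and 88.4%. It called 42 and 30 of 134110 probe sets left unchanged. In the long term comparison, with 12263 genes, a list lowered by 1 on the log2 scale passed in 5 of 5 runs and 0 of 130 other lists did. The real long term list medians were smaller, from -0.35 to 0.46. Both steps drew each probe set or gene independently. Real values vary together, and another grouping of the short term arrays called 16570 probe sets. The simulated false calls therefore hold for independent noise alone.

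The alternatives fixed beforehand were median centring, a pseudocount of 1 or 64, no filter, the upper 40%, probe sets averaged per gene, and each time point fitted alone. Further ones were the replicate number as a block, array weights, a trended robust variance, the scanner as a block, the long term arrays of 1 scanner, and each array left out in turn. Chosen after seeing the data were no normalization between arrays, the hybridisation controls as a covariate or as 2 strata, and the short term arrays with weak hybridisation controls alone. So were the endothelial markers as a covariate, the long term arrays without knockdown 1 and control 1, and array weights estimated gene by gene. Zfp335 had 1 probe set, so no other probe set could be tried for it. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.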

Results

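The title of the series asks how ZNF335 acts on stem cell proliferation and neuronal differentiation through the trithorax complex, which methylates histone H3, and through REST/NRSF, a repressor of neuronal genes. Expression of sorted mouse cells was profiled on 12 arrays, 3 knockdown and 3 control samples at 1 day and 3 and 3 at 5 days after knockdown. The knockdown and control samples of each time point, the difference between the time points' effects, and the controls of both time points were compared.

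Zfp335 itself, read by 1 probe set, was not shown to differ between knockdown and control at either time point when the main fit was run without the filter. Its deposited signal was 136, 53.7 and 41.0 in the short term knockdowns and 139, 46.1 and 127 in the short term controls (76.9 ± 51.7 against 104 ± 50.6, SD, n = 3 each). In the long term samples it was 103, 34.3 and 151 in the knockdowns and 109, 150 and 179 in the controls (96.2 ± 58.8 against 146 ± 35.2, SD, n = 3 each). The limma log2 fold change was -0.64 (SE 0.73, 95% interval -2.26 to 0.97, adjusted p = 0.917, exact permutation p = 0.7) in the short term and -0.64 (SE 0.73, interval -2.25 to 0.98, adjusted p = 1, exact permutation p = 0.4) in the long term. The intervals held both no change and a fall by more than 4-fold, and where the hairpin's target lies relative to the probe set is not given in the sources used here. The signals of the groups overlapped in both time points. Short term knockdowns 1 and 2 and long term knockdown 3 lay within the control range. Short term controls 2 and 3 and long term controls 1 and 2 lay within the knockdown range. The target therefore did not check the labels, and groups below are those of the titles, which for the long term samples the description field contradicts.

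**Figure D1:**
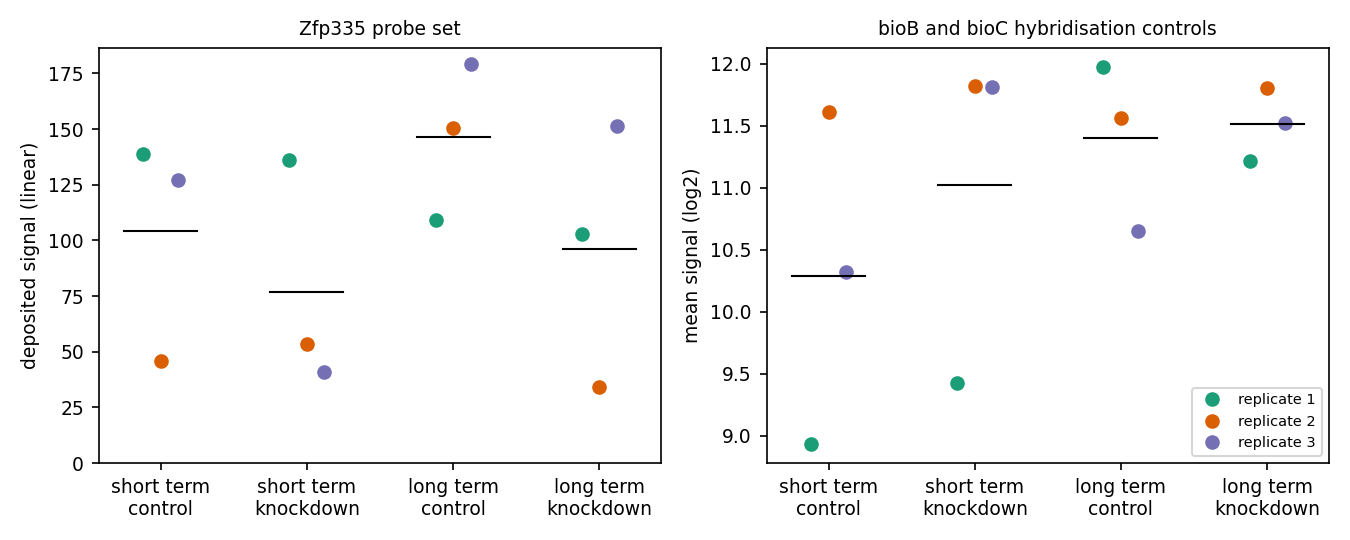
Deposited signal of the Zfp335 probe set on a linear axis (left) and mean log2 signal of the bioB and bioC hybridisation controls (right) for the 12 arrays, coloured by replicate number, with group means as lines. Short term control 2 lay at 46.1 for Zfp335, near knockdowns 2 and 3 at 53.7 and 41.0, and these 3 arrays had the brightest short term hybridisation controls, 11.61 to 11.82.

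The short term arrays fell into 2 sets of 3 that crossed the groups. Knockdowns 2 and 3 and control 2 had hybridisation controls, RNAs added in fixed amounts, at 11.61 to 11.82 on the log2 scale, and knockdown 1 and controls 1 and 3 had them at 8.93 to 10.32. Correlations were 0.975 to 0.978 and 0.923 to 0.989 within the sets and 0.597 to 0.775 between them. Microglial markers averaged 5.60 to 5.74 on the log2 scale in the set with strong controls, and 7.53, 8.25 and 8.07 in knockdown 1, control 1 and control 3. In the long term arrays these markers averaged 10.26, 7.94 and 8.68 in the controls and 11.07, 9.22 and 7.65 in the knockdowns. Endothelial markers averaged 10.48, 7.69 and 8.68 against 11.10, 9.02 and 7.65. Long term knockdown 2 had an Actb 3 prime to 5 prime ratio of 8.76 and a Gapdh ratio of 3.90, against 1.51 to 2.91 and 1.65 to 2.22 in the other 11 arrays. All short term arrays shared a scanner, with station 7 for the knockdowns and 8 for the controls, so fluidics station and group cannot be told apart there. The long term knockdowns and control 1 were read on 1 scanner and controls 2 and 3 on another.

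At 1 day after knockdown, no gene passed the test. Among genes whose 3 knockdown values lay above all control values without passing, Fbxw17 had a log2 fold change of 0.81 (SE 0.29), Urah, an enzyme of uric acid breakdown, 0.87 (SE 0.32), and Ldlrad4, an inhibitor of TGF-beta signalling, 0.98 (SE 0.42). Casq2 (0.70), Glb1l2 (0.60), Rbbp6 (0.67), the calcium-dependent kinase gene Camk4 (0.64), Ogn (0.59) and Pdia4 (0.81) had like values. On the lower side stood Ung, which removes uracil from DNA, at -0.75 (SE 0.30), the kinetochore gene Spc24 at -0.64 (SE 0.24), and the interferon-induced Ifitm3 at -1.03 (SE 0.63). Uckl1 (-0.63), Samd11 (-0.63), Mtap (-0.58), Galt (-0.76), Cdca7l (-0.61), Cntfr (-0.66), Bckdhb (-0.62), Pgm1 (-0.62) and Rhcg (-0.80) completed the 12. Without control 3 Rbbp6, Camk4, Pdia4 and Ifitm3 had 0.38, 0.35, 0.40 and -0.60, and without control 1 Ogn had 0.39. Without knockdown 2 Uckl1 and Bckdhb had -0.39 and -0.35, and without knockdown 3 Cdca7l, Cntfr and Rhcg had -0.36, -0.40 and -0.39. Rest had 0.24 (SE 0.33, adjusted p = 0.833), reversed in sign among the arrays with weak hybridisation controls (-0.12), where knockdown 1 was the single knockdown against controls 1 and 3 and is assumed to vary like the other groups.

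By limma, 0 of 27022 probe sets passed (smallest adjusted p = 0.832), and 120 had an unadjusted p below 0.05, 59 higher and 61 lower. Of the kept probe sets, 451 (1.67%) did not overlap between the groups, where chance gives 10%. Each list had 0 members past the threshold over all genes and 0 adjusted over the list alone. None of the 27 lists passed with the preset correlation, an estimated one or fry (smallest adjusted p = 0.385, 0.984 and 0.879), while leaving out control 1, control 3 or knockdown 3 gave 4, 4 and 2 lists past the threshold with the preset one. All 12 measured microglial markers were lower (median -1.12, adjusted p = 0.385; C1qb -2.07, SE 1.52, Csf1r -1.75, SE 1.32). Leaving out 1 array, C1qb ran from -3.51 to -1.27 and Csf1r from -2.98 to -1.11. All kept probe sets had a median of -0.098, and all genes -0.16 with probe sets averaged per gene, so a list median near these is not particular to the list. Of the list of intermediate progenitors and newborn neurons 14 of 15 were lower (median -0.16, adjusted p = 0.768). Also lower were 20 of 25 DNA replication genes (median -0.22, adjusted p = 0.573; Mcm5 -0.50, SE 0.24) and 10 of 10 RNA interference genes (median -0.29, adjusted p = 0.385). The REST corepressor list had a median of -0.059 (adjusted p = 0.813), the RE1 genes -0.37 (adjusted p = 0.768) and the trithorax list -0.19 (adjusted p = 0.573). In the last Men1 had -0.75 (SE 0.48), and -1.24 to -0.50 with 1 array left out. The RE1 median was -0.54 without control 3 (adjusted p = 0.0459), but 0.34 among the arrays with weak hybridisation controls, which hold 1 knockdown. Synaptic, postmitotic neuron and deep-layer medians were -0.35, -0.16 and -0.18 with all arrays and 0.30, 0.13 and 0.32 among the weak-control arrays. Camera compares the test statistics of a list with those of the other genes, and the median of all genes was itself below 0 here. Camera's direction was up although the list median was negative for the REST corepressor, deep-layer, upper-layer, p53, Notch and Wnt, axon and ribosomal lists. The same held for the interferon, immediate-early, Cajal-Retzius, astrocyte and meningeal lists, the last with a mean above 0, and the apical progenitor and interneuron lists had a mean below 0 with an upward direction. Estimated array weights, which gave knockdown 1 and control 2 weights of 0.143 and 0.220, ended the count of 0, with 21029 probe sets past the threshold.

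At 5 days after knockdown, no single gene passed the test. Genes of newborn neurons and of intermediate progenitors, the dividing cells between radial glia and neurons, were lower as a list (adjusted p = 6.31e-07 with the preset correlation, and adjusted p = 0.285 with an estimated correlation). Of its 15 measured members 13 were lower in the knockdown (median log2 fold change -0.35), beside 14 in the short term (median -0.16, list not past the threshold). The short term median was like that of all genes, -0.16 with probe sets averaged per gene. The list also had a median of -0.39 in short term knockdowns 2 and 3 and control 2 against the other short term arrays. The short term count is therefore no separate evidence of a fall. The long term list mean was 8.97, 9.19 and 9.28 in the 3 knockdowns against 9.36, 9.54 and 9.51 in the 3 controls. Eomes, a transcription factor that marks these cells, stood at -0.84 (SE 0.26, n = 3 each; limma unadjusted p = 0.00869, adjusted p = 1), 9.33 ± 0.39 against 10.17 ± 0.24 on the log2 scale. Neurod4 (-0.62, SE 0.26), the proneural factor Neurog2 (-0.51, SE 0.23) and Gadd45g (-0.72, SE 0.42, and -0.37 without knockdown 2) had like values. Leaving out 1 array at a time gave the list an adjusted p of 4.02e-13 to 0.0361 with the preset correlation, and the scanner as a block gave a median of -0.24 and an adjusted p of 0.00112, with control 1 as the single control on the knockdowns' scanner, assumed to vary like the other groups.

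**Figure D2:**
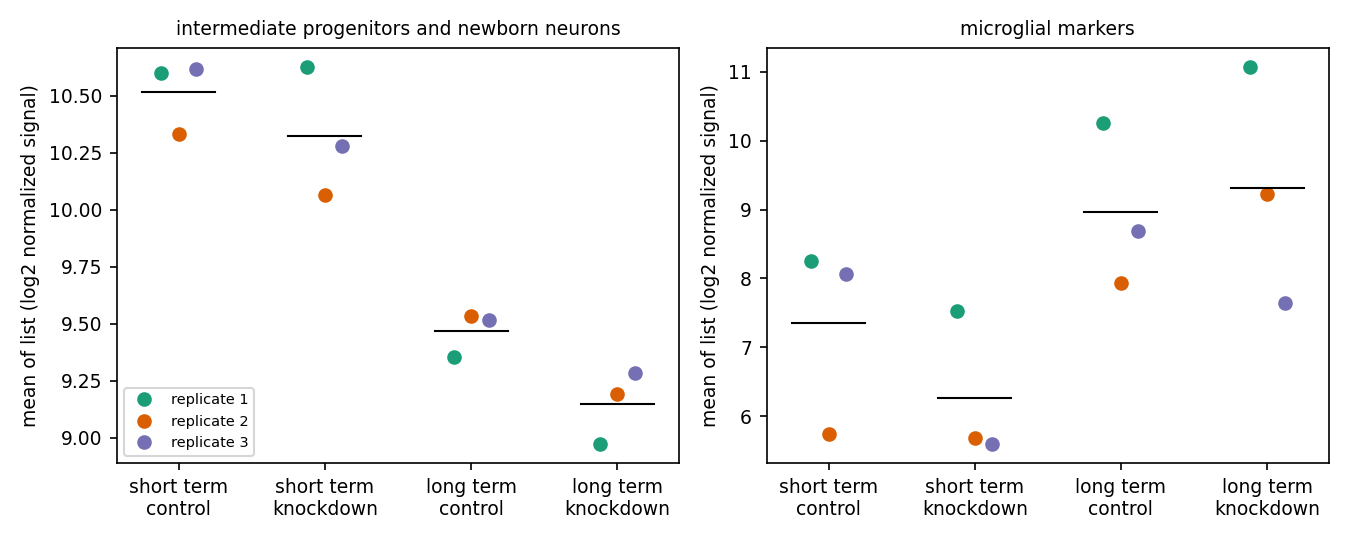
Mean log2 normalized signal of the intermediate progenitor list (left) and of the microglial markers (right) per array, coloured by replicate number, with group means as lines. The 3 long term knockdowns lay at 8.97 to 9.28 for the intermediate progenitor list, below the 3 long term controls at 9.36 to 9.54, while the microglial markers ranged from 7.65 to 11.07 within the long term knockdowns.

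Other genes whose long term values did not overlap, without passing, were on the lower side A930024E05Rik (-0.91, SE 0.29), Parm1 (-0.85, SE 0.32), Zfp626 (-0.93, SE 0.36), Tfap2d (-0.65), the REST corepressor Rcor2 (-0.74, SE 0.34), Sox8 (-0.62), Zfyve27 (-0.60), Gm11110 (-0.62), Zfp58 (-0.82) and 1700061N14Rik (-0.69). On the higher side were Arsa, a lysosomal sulfatase (0.68, SE 0.29), Plekha2 (0.84, SE 0.45), the nuclear receptor Rora (0.70, SE 0.55), Crispld2 (1.01), Ccdc173 (0.63), A530088E08Rik (0.89), Lmntd2 (0.82), 3930402G23Rik (0.62), Fam151a (0.60), Fpr2 (0.82), Greb1l (0.72) and Glis3 (0.74). Without knockdown 2, the array with the high 3 prime ratios, several of these values were smaller by more than 1.5 times. On the higher side Crispld2 had 0.26, Lmntd2 0.22, A530088E08Rik 0.28, Fam151a 0.25, 3930402G23Rik 0.31, Ccdc173 0.35, Arsa 0.38 and Greb1l 0.38. On the lower side Gm11110 had -0.30, Zfyve27 -0.34, Zfp58 -0.34, Tfap2d -0.37 and Sox8 -0.37. Without control 1 Glis3 had 0.48. Rest had 0.38 (SE 0.33, adjusted p = 1), which turned to -0.058 with the scanner as a block. By limma, 0 of 27022 probe sets passed (smallest adjusted p = 1), 34 had an unadjusted p below 0.05, and 813 (3.01%) did not overlap, where chance gives 10%. The long term arrays fitted alone had 0 past the threshold, 84 at an unadjusted p below 0.05 and a median SE of 0.28. In the joint fit the median SE was 0.41, since the short term arrays varied more (0.44 fitted alone).

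Beside the intermediate progenitors, 8 lists passed with the preset correlation, 7 lower and 1 higher. None of the 9 passed with an estimated correlation or with fry (smallest adjusted p = 0.285 and 0.968). Of the 10 groupings of the long term arrays, the real one included, 5 passed at least 9 lists with the preset correlation. Each list had 0 members past the threshold over all genes and 0 adjusted over the list alone. Ribosomal protein genes were lower in 17 of 19 (median -0.28, adjusted p = 9.96e-07, and adjusted p = 0.585 with an estimated correlation; Rps19 -0.59, Rpl8 -0.56). Without knockdown 2 that median was 0.020 (adjusted p = 0.734), Rps19 had 0.00032 and Rpl8 -0.021, and under the scanner block the adjusted p was 0.190. DNA replication genes were lower in 21 of 25 (median -0.21, adjusted p = 6.83e-05, and adjusted p = 0.585 with an estimated correlation; Rfc3 -0.76, E2f1 -0.75). They had a median of 0.0073 and an adjusted p of 0.806 under the scanner block, and an adjusted p of 0.225 without control 3. Without knockdown 2 their median was -0.14, with -0.23 for Rfc3 and -0.20 for E2f1. Trithorax genes were lower in 17 of 22 (median -0.12, adjusted p = 0.0135, and adjusted p = 0.813 with an estimated correlation; Setd1a -0.40, Wdr5 -0.39). Their adjusted p was 0.393 without knockdown 1, 0.0531 without control 2 and 0.548 under the scanner block. Without knockdown 2 their median was -0.060, with -0.14 for Setd1a and -0.053 for Wdr5. The ribosomal median was -0.50 without knockdown 1, that of DNA replication genes -0.33 without control 1 and -0.033 without control 3, and that of trithorax genes -0.21, -0.073, -0.074 and -0.075 without control 1, 2 or 3 or knockdown 1.

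Respiratory chain genes were lower in 20 of 26 (median -0.10, adjusted p = 0.0136, and adjusted p = 0.813 with an estimated correlation; Cox4i1 -0.61). Their adjusted p was 0.979 without knockdown 2, where Cox4i1 had -0.011, 0.264 without control 3 and 0.875 under the scanner block, and the median was -0.0089, -0.023, -0.19 and -0.17 without knockdown 2, control 3, control 1 or knockdown 1. G2/M genes were lower in 18 of 26 (median -0.11, adjusted p = 0.0264, and adjusted p = 0.819 with an estimated correlation; Birc5 -0.41, Ube2c -0.51). That call was lost without knockdown 1, 2 or 3 (adjusted p = 0.126, 0.0615 and 0.0908), without control 3 (0.715), with the replicate block (0.0584) and with the scanner block (0.552). The median was -0.19 without control 1 and -0.038 without control 3, and without knockdown 2 Birc5 had -0.17 and Ube2c -0.040. Immediate-early genes were higher in 13 of 17 (median 0.20, adjusted p = 0.0135, and adjusted p = 0.585 with an estimated correlation; Klf6 0.47, Egr2 0.56). They were not past without control 2 (0.60, where Egr2 had 0.21), knockdown 1 (0.578) or knockdown 3 (0.188), and had a median of -0.39 under the scanner block (adjusted p = 0.253). Their median was 0.46 without knockdown 2 (adjusted p = 3.26e-09), 0.34 without control 1, and 0.0097, 0.015 and 0.13 without control 2, knockdown 1 or knockdown 3. Interneuron markers were lower in 9 of 12 (median -0.27, adjusted p = 0.0252, and adjusted p = 0.813 with an estimated correlation; Dlx6 -0.53). They were not past the threshold without controls 1 or 2 (0.0524 and 0.0531) or knockdowns 1 or 3 (0.578 and 0.868), nor under the scanner block (0.253). Without knockdown 2 their median was -0.66 (adjusted p = 1.83e-13), and without knockdown 1 or 3 it was -0.053 and -0.15. Oligodendrocyte precursor markers were lower in 8 of 8 (median -0.25, adjusted p = 0.0277, and adjusted p = 0.585 with an estimated correlation; Olig1 -0.45). That call was not kept without control 3 (0.133), knockdown 1 (0.578, where Olig1 had -0.25) or knockdown 2 (0.111), nor under the scanner block (0.424), and the median was -0.14, -0.16 and -0.50 without knockdown 1, 2 or 3. Array weights ended the ribosomal, DNA replication, respiratory chain and G2/M calls (0.215, 0.0576, 0.384 and 0.377). With no filter the immediate-early, interneuron and oligodendrocyte precursor lists had 0.0685, 0.0714 and 0.0714. Probe sets averaged per gene gave 0.0542 for the respiratory chain, 0.121 for G2/M and 0.0544 for oligodendrocyte precursors. Without normalization between arrays G2/M, immediate-early and oligodendrocyte precursor genes had 0.0890, 0.124 and 0.126. The long term arrays fitted alone gave 0.0532 for both the respiratory chain and G2/M.

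The REST corepressor list had a long term median of -0.089 (adjusted p = 0.179) and the RE1 genes 0.047 (adjusted p = 0.945), with a downward test direction for the latter. Microglial markers were higher in 11 of 12 (median 0.34, adjusted p = 0.179) and endothelial markers in 12 of 15 (median 0.46, adjusted p = 0.179). With the scanner as a block their medians were -1.01 and -1.22 (adjusted p = 0.00015 and 1.26e-07), and without control 1 they were 1.04 and 1.23 (adjusted p = 0.000102 and 2.42e-05) and without knockdown 3 1.17 and 1.28 (adjusted p = 5.85e-05 and 0.000101). The apical progenitor list (median -0.036, adjusted p = 0.576), postmitotic neurons (-0.049, 0.661), upper-layer (-0.085, 0.750), deep-layer neurons (0.041, 0.179), microcephaly genes (0.045, 0.325) and p53 targets (0.075, 0.359) did not pass either. Nor did Notch and Wnt components (-0.036, 0.913), axon guidance (-0.0044, 0.855), synaptic genes (-0.14, 0.247), the interferon list (0.13, 0.559), RNA interference (-0.014, 0.750), Cajal-Retzius (0.26, 0.179), astrocyte (0.011, 0.750) and meningeal markers (0.30, 0.184). The upper-layer and axon lists had a mean above 0 and a downward test direction, and the astrocyte list a mean below 0 and a median above 0. Without knockdown 2 several of these lists did pass, with medians of 0.14 for apical progenitors (adjusted p = 0.00161), 0.13 for p53 targets (0.00161), 0.18 for Notch and Wnt components (0.000142), 0.21 for the interferon list (0.0147), 0.40 for endothelial (0.0287) and 0.21 for astrocyte markers (0.0272). On the lower side were postmitotic neurons at -0.14 (0.000118), upper-layer neurons at -0.12 (0.0311), RE1 genes at -0.11 (0.0445), axon guidance at -0.12 (0.00161) and synaptic genes at -0.17 (0.0287). Without knockdown 3 apical progenitors passed on the lower side (-0.19, 0.00467), and Cajal-Retzius (0.62, 0.0212) and meningeal markers (0.46, 0.0253) on the higher side.

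The difference between the long term and short term effects held no gene past the threshold. The histone gene H1f2 had a difference of 2.02 (SE 0.71), Naf1 of 0.82 (SE 0.31), Fbxo6 of 1.20 (SE 0.47), Cpt1a, which carries fatty acids into mitochondria, of 1.04 (SE 0.43) and Baiap2l1 of 1.13 (SE 0.48). Zfp133-ps had -1.41 (SE 0.54), 1700061N14Rik -1.35 (SE 0.52), Arrdc4 -0.70 (SE 0.29), Zfp626 -1.16 (SE 0.51, and -0.77 without short term knockdown 1) and the neurite outgrowth gene Nrn1 -0.65 (SE 0.30). Eomes had -0.68 (SE 0.37), Csf1r 2.60 (SE 1.86) and Rest 0.14 (SE 0.47, and -0.30 with the scanner as a block). By limma, 0 of 27022 probe sets passed (smallest adjusted p = 1) and 55 had an unadjusted p below 0.05. Of the lists, 5 passed with the preset correlation and 0 with an estimated one or fry (smallest adjusted p = 0.497 and 0.949), and each had 0 members past over all genes and 0 adjusted over the list alone. Ribosomal protein genes had a median difference of -0.28 (0.066 without long term knockdown 2, adjusted p = 0.690) and microglial markers of 1.39 (0.59 without long term knockdown 1, adjusted p = 0.844, and 0.12 with the scanner as a block). Leaving out 1 array gave from 1 list, without long term knockdown 1, to 11, without short term control 3. The test direction was down while the list median was above 0 for the upper-layer, G2/M, REST corepressor, trithorax, Notch and Wnt, axon, synaptic, respiratory chain and meningeal lists. The median of all genes was itself above 0, at 0.10 with probe sets averaged per gene. Array weights called 10712 probe sets.

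Between the short term and the long term controls, 886 probe sets passed, 547 higher (445 genes) and 339 lower (273 genes) in the long term. The short term and long term arrays may have been run in different months. They had no chip lot in common and differed in level in the deposited table, so time and batch cannot be told apart. Intermediate progenitor genes were lower in 12 of 15 (median -1.02), 6 past the threshold and 10 adjusted over the list alone. Nhlh1 fell by 4.04 on the log2 scale (SE 0.40, adjusted p = 0.00033), Neurog2 by 2.04 (SE 0.23, adjusted p = 0.000968) and Eomes by 1.69 (SE 0.26, adjusted p = 0.00733). The list had an adjusted p = 5.70e-08, and adjusted p = 0.109 with an estimated correlation. Cell division genes were lower too. Of the G2/M list 26 of 26 were lower (median -1.06, adjusted p = 7.95e-19, and adjusted p = 0.109 with an estimated correlation), 10 past the threshold and 22 adjusted over the list alone (Tpx2 -1.37, Bub1 -1.5). Of the DNA replication list 24 of 25 were lower (median -0.75, adjusted p = 5.38e-11, and adjusted p = 0.112 with an estimated correlation), 5 past and 13 adjusted over the list alone (Mcm5 -1.57, Mcm2 -1.64, Cdt1 -1.53). Without normalization between arrays, which moved the median of all kept probe sets from 0.0028 to 0.87, Tpx2 had 0.074, still below that median. Bub1, with 1 array left out, was past the threshold in 4 of 6 fits (adjusted p up to 0.0589) and not without long term control 1 or 2. Mcm2 and Cdt1 were past in 2 of 6 (up to 0.0860 and 0.0858), without short term control 1 and without long term control 3.

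Markers of interneurons and glia were higher in the long term controls. Of the interneuron list 11 of 12 were higher (median 2.07, adjusted p = 2.01e-08, and adjusted p = 0.230 with an estimated correlation), 7 past the threshold and 9 adjusted over the list alone. Among them were the transcription factors Dlx2, up by 4.90 (SE 0.46, adjusted p = 0.000243), and Dlx1, up by 4.68 (SE 0.69, adjusted p = 0.00603), and Gad1, which makes GABA, up by 2.81 (SE 0.58, adjusted p = 0.0295). Of 8 oligodendrocyte precursor markers 8 were higher (median 1.70, adjusted p = 7.23e-06, and adjusted p = 0.0967 with an estimated correlation), 2 past and 5 adjusted over the list alone (Olig1 3.96, Pdgfra 4.23). Of 10 astrocyte markers 10 were higher (median 1.53, adjusted p = 0.000122, and adjusted p = 0.109 with an estimated correlation), 3 past and 5 adjusted over the list alone (the water channel gene Aqp4 2.57, Gfap 2.80, Sparcl1 2.93). Microglial markers were higher in 12 of 12 (median 1.5, adjusted p = 0.0225, and adjusted p = 0.591 with an estimated correlation), with 0 past in either adjustment. Endothelial markers were higher in 15 of 15 (median 1.36, adjusted p = 0.0432, and adjusted p = 0.616 with an estimated correlation), with 1 past in either (Slco1c1 3.43, adjusted p = 0.0169). Without normalization between arrays these 2 lists had medians of 2.56 and 1.83, above the 0.87 of all probe sets, but were not past the threshold (adjusted p = 0.290 and 0.148) and camera's direction was down. Gfap, with 1 array left out, was past in 0 of 6 fits (adjusted p from 0.0748 to 0.165), Gad1 in 1 (up to 0.130), Sparcl1 in 2 (up to 0.0786) and Slco1c1 in 4 (up to 0.0847). Gad1 was past without short term control 1, Sparcl1 without short term control 1 or 2, and Slco1c1 in all but those without long term control 1 or 3.

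Upper-layer genes were higher in 10 of 14 (median 0.63, adjusted p = 0.0110, and adjusted p = 0.243 with an estimated correlation), 1 past and 5 adjusted over the list alone (Cux2 1.60). Deep-layer genes were lower in 11 of 13 (median -0.45, adjusted p = 0.0432, and adjusted p = 0.551 with an estimated correlation), 2 past and 4 adjusted over the list alone (Fezf2 -2.35, Pcp4 -1.42), beside 1 higher in the latter. RE1 genes were higher in 25 of 32 (median 0.62, adjusted p = 0.0110, and adjusted p = 0.591 with an estimated correlation), 4 past and 4 adjusted over the list alone (Syt4 1.24, Gria2 1.32). Immediate-early genes were higher in 14 of 17 (median 0.93, adjusted p = 0.00358, and adjusted p = 0.284 with an estimated correlation), 3 past and 7 adjusted over the list alone (Fos 2.09, Klf6 1.27). Axon guidance genes were higher in 20 of 26 (median 0.38, adjusted p = 0.0473, and adjusted p = 0.579 with an estimated correlation), 1 past and 2 adjusted over the list alone (Robo1, a receptor for the guidance cue Slit, 1.83). Microcephaly genes were lower in 12 of 14 (median -0.60, adjusted p = 0.000749, and adjusted p = 0.299 with an estimated correlation), 0 past and 4 adjusted over the list alone. Respiratory chain genes were lower in 23 of 26 (median -0.28, adjusted p = 0.000207, and adjusted p = 0.550 with an estimated correlation), and without normalization between arrays a median of 1.02, above the 0.87 of all probe sets. Ribosomal protein genes were lower in 18 of 19 (median -0.25, adjusted p = 0.00815, and adjusted p = 0.591 with an estimated correlation). Both had 0 past in either adjustment. REST corepressors had a median of -0.10 (adjusted p = 0.105), 1 past and 3 adjusted over the list alone, all lower (Hdac1 -1.07, adjusted p = 0.0182). Rest had 0.15 (SE 0.33, adjusted p = 0.883), with a sign that other settings turned. With 1 array left out, Fezf2, Pcp4, Syt4, Gria2 and Fos were past in 0 of 6 fits (adjusted p up to 0.186, 0.188, 0.127, 0.171 and 0.152). Hdac1 was past only without short term control 2 (up to 0.0974), Robo1 only without short term control 1 or 2 (up to 0.128), and Klf6 in all but those without short term control 3 and long term controls 1 and 3 (up to 0.0732).

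By the naming rule, the genes of the largest change were higher in 1700065D16Rik (6.52), Gm5802 (6.34), Rpl39 (5.65), Macroh2a3 (5.62) and Chmp4c (5.11), and lower in Gm34303 (-5.06), 4930448K20Rik (-4.65), Fam219a (-4.64), Gm16740 (-4.32) and Mab21l2 (-4.08). Of these 10, Mab21l2 lost the call with 1 array left out, in all but the fit without short term control 1 (adjusted p up to 0.178). By limma, 4650 probe sets had an unadjusted p below 0.05, and 8049 (29.8%) did not overlap, where chance gives 10%. With the preset correlation 16 of 27 lists passed, 9 higher and 7 lower, none with an estimated correlation and 9 with fry. Without normalization between arrays 13122 probe sets passed, 12860 of them higher. Leaving out short term control 1, 2 or 3 left 614, 533 and 302 probe sets, and leaving out long term control 1, 2 or 3 left 279, 247 and 305. The highest adjusted p with 1 array left out was 0.162 for deep-layer genes (short term control 2), 0.0898 for RE1 genes and 0.0973 for axon guidance (short term control 3), and 0.218 for microglial and 0.472 for endothelial markers (long term control 1).

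**Figure D3:**
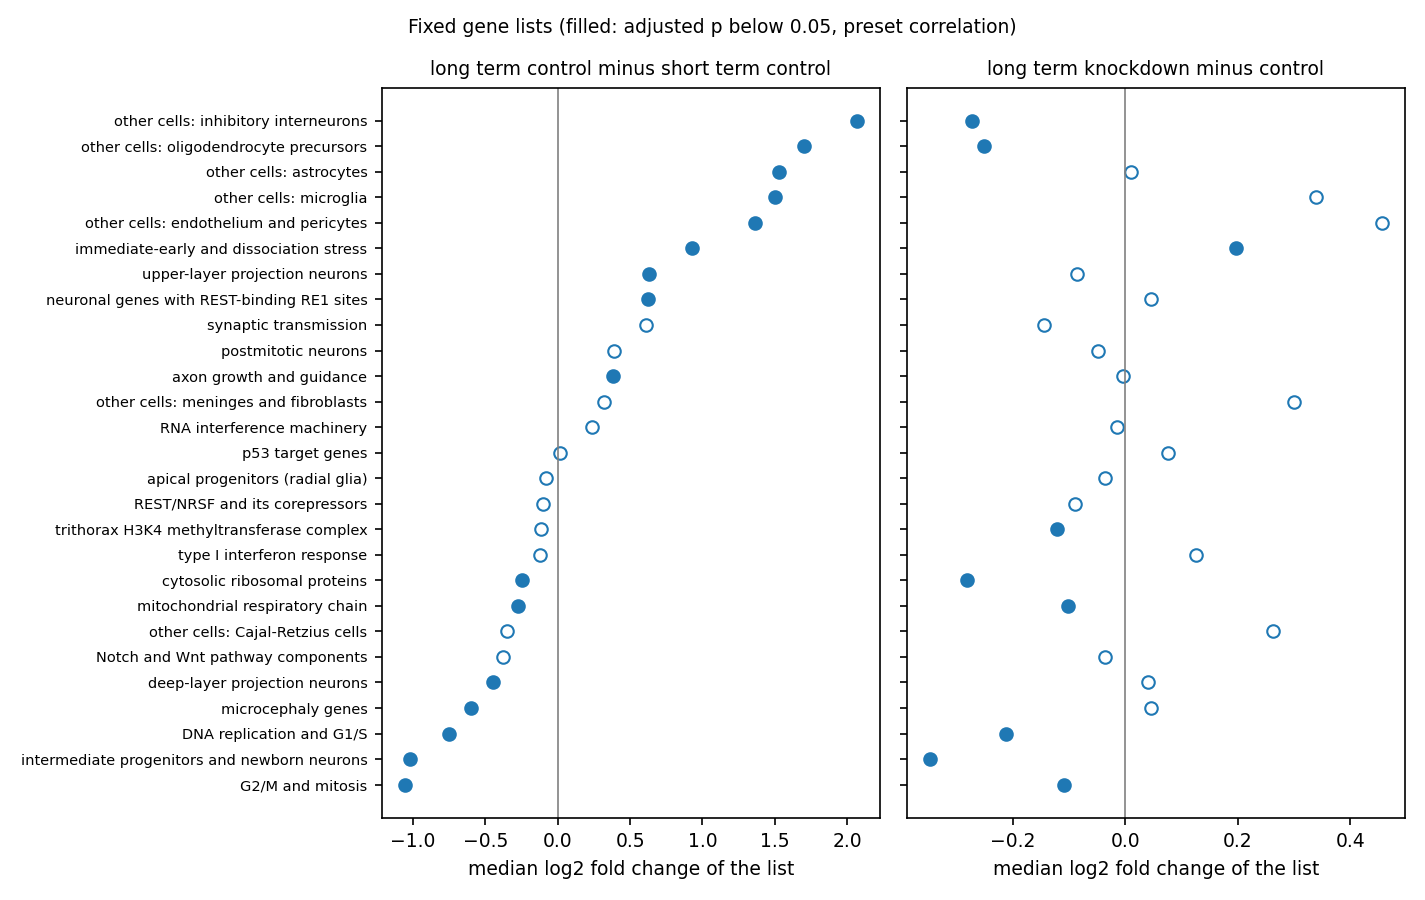
Median log2 fold change of each tested gene list for long term minus short term controls (left) and long term knockdown minus control (right), filled where the adjusted p with the preset correlation was below 0.05. Medians ran from -1.06 to 2.07 on the left and from -0.35 to 0.46 on the right.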

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

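The difference between the time points' effects, the estimated correlation, the arrays left out and the arrays of one scanner were planned, while their use to weigh an explanation, the tests of the hybridisation controls, the RE1 genes, the exchanged labels, dilution and older cells, and the regroupings were chosen after the results they bear on were seen. For 5 lists the long term effect differed from the short term effect with the preset correlation. With an estimated correlation none passed, with adjusted p = 0.497 for oligodendrocyte precursors and 0.954 for the other 4. With the preset correlation intermediate progenitor genes had an adjusted p = 0.00815 (median difference -0.12, 15 genes) and ribosomal protein genes 5.32e-05 (-0.28, 19 genes), both down. Microglial markers had 0.0176 (1.39, 12 genes, up), interneuron markers 0.0256 (-0.23, 12 genes, down) and oligodendrocyte precursor markers 0.00617 (-0.45, 8 genes, down). Leaving out 1 array ended each of these calls at least once. Intermediate progenitors were lost without short term control 2 (0.127), short term knockdown 1 (0.272) or long term knockdown 1 (0.212), ribosomal genes without long term knockdown 2 (0.690) and oligodendrocyte precursors without long term knockdown 1 (0.212). Microglial markers were lost without short term control 1 (0.0866) or knockdown 1 (0.215), and without long term control 2 (0.320), control 3 (0.108), knockdown 1 (0.844) or knockdown 2 (0.0504). Interneuron markers were lost without short term control 2 (0.147), control 3 (0.167) or knockdown 1 (0.859), and without long term control 2 (0.0523), control 3 (0.0619), knockdown 1 (0.312) or knockdown 3 (0.463). Without short term knockdown 1 the intermediate progenitor and interneuron medians were 0.071 and 0.23, and over the other arrays left out they ran from -0.32 to -0.028 (short term knockdown 2 and control 2) and from -0.49 to -0.058 (long term knockdown 2 and short term control 3). The ribosomal median was 0.066 without long term knockdown 2, -0.45 without long term knockdown 1 and -0.18 without short term control 2 or knockdown 1. The microglial median ran from 0.59 without long term knockdown 1 to 2.22 without short term control 2. Under the scanner block none of the 5 passed (0.161 to 0.473).

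Of 100 groupings, the real one included, 59 passed at least as many lists as the real 5, with a highest other of 17, so chance was not excluded for the lists. The real count of probe sets was 0, which all 100 groupings reach (highest other 15495), so that comparison decides nothing.

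The first pattern was the parting of the short term arrays into sets that crossed the groups, knockdowns 2 and 3 with control 2 against the others. In the set with strong hybridisation controls 25.5% of kept probe sets were lower and 19.9% higher by at least 1 on the log2 scale, and the grouping that follows the sets called 16570 probe sets where the real one called 0, which describes the same structure of the samples and is no separate evidence. A difference in labelling or hybridisation stays open: the lowest control of one set lay 1.29 above the highest of the other. The long term arrays, with controls at 10.65 to 11.98, correlated less with the strong set (0.552 to 0.738) than with the weak set (0.731 to 0.918). That correlation cannot decide the question, since deposited levels differed between the time points (trimmed means of 186 to 239 and 451 to 529). The controls of the long term arrays are therefore not on the scale of the short term sets. Microglia in the other set alone would not lower neuronal genes here, but RE1 genes had a median of -0.93 (27 of 32 lower) while apical progenitor genes had 0.29 (15 of 20 higher). The exact permutation p was 0.1 for the RE1 list, the smallest possible with 3 arrays a set. Falls were wide, with a median of -0.71 for the 1000 probe sets nearest to Zfp335 in level. RE1 genes were not compared with probe sets of like level, so their median does not single out neuronal genes. Another mix of cells stays open. Exchanged labels of knockdown 1 and control 2 cannot be told apart from these: Zfp335 was lower by -2.11 in the strong set, but 9.8% of the 1000 probe sets nearest in level were as low or lower.

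The second pattern was the lower intermediate progenitor list in the long term knockdown. RNA quality of knockdown 2 does not account for it, since the list had -0.35 without that array and the other knockdowns, at 8.97 and 9.28, lay below all 3 controls. Dilution by cells that lack apical progenitor and neuron genes would lower these alike, but those 37 genes had a median of -0.049, against -0.35 for the list. Dilution by cells that express some of them would not, and Aldoc stands in both the apical progenitor and the astrocyte list. Within arrays the list lay further below them in the knockdown, by -0.26 on average (-1.83, -1.51 and -1.71 against -1.50, -1.29 and -1.47). Knockdown 3 had the lowest microglial and endothelial means of the long term arrays (7.65 and 7.65), with the list at 9.28, below all 3 controls. Knockdown 2 and control 1 nearly coincided in the within-array difference (-1.51 and -1.50). The exact permutation p of 0.1 is the smallest that 3 against 3 allow, so dilution was not excluded. The scanner cannot be told apart from the knockdown as a source, because among the arrays of one scanner the list had -0.24 with control 1 as the single control, and older cells stay open too, since oligodendrocyte precursor markers, which would be higher, were at -0.25 but with an adjusted p = 0.585 with an estimated correlation. A fall of these cells after loss of ZNF335 remains a hypothesis, with no fall of Zfp335 shown and no list past the threshold with an estimated correlation.

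The third pattern was the lower ribosomal protein list in the long term knockdown. Degraded RNA in knockdown 2 is a candidate explanation: without that array the median was 0.020 and the adjusted p = 0.734, and that array had the highest 3 prime to 5 prime ratios. With the 2 other knockdown arrays, no effect of the knockdown on these genes was detected apart from it.

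For the other comparisons the 10 possible regroupings of 3 against 3 are too few for a share under 0.05. The real and the highest other count of probe sets were 0 and 16570 in the short term, 0 and 0 in the long term, and 886 and 0 between the controls. For lists they were 0 and 10, 9 and 13, and 16 and 14. In the long term 5 of the 10 groupings, the real one included, passed at least as many lists as the real 9. Chance was therefore not excluded for the long term lists.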

How the results depend on the processing

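The alternatives without normalization, with hybridisation controls, weak-control arrays or endothelial markers, without knockdown 1 and control 1, and with weights gene by gene were chosen after seeing the data. The short and long term counts of 0 probe sets held in every other setting run, except that array weights called 21029 and weights gene by gene 16466 in the short term; the difference had 0 except 10712 and 11387 with these. The first weights ran from 0.00347 to 34.3, a range that trusts single arrays. Leaving out 1 array gave 0 to 0 in these comparisons. Between the controls the 886 probe sets (547 higher, 339 lower) became 4844 with median centring, 1702 with no filter, 528 genes with probe sets averaged, 16962 (8309 higher, 8653 lower) with array weights, 1370 with a trended robust variance. They became 279 with the scanner as a block (the same as without long term control 1), 13122 (12860 higher, 262 lower) without normalization, 10709 (5814 higher, 4895 lower) with the hybridisation covariate and 7267 with weights gene by gene, and 247 to 614 with 1 array left out, where fewer samples were used. Otherwise the cause was not tested.

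Zfp335 in the short term had -1.97 (adjusted p = 1.53e-05) with array weights and -1.90 (adjusted p = 0.00197) gene by gene, but 0.065 with the hybridisation strata as a block and 0.13 among the arrays with weak controls. The weights of knockdown 1 and control 2 were 0.143 and 0.220, and 0.101 and 0.156 gene by gene. The weighted fits thus mostly compared the 2 sets of short term arrays again and are no separate evidence of a fall. With 1 array left out Zfp335 had -1.37 to -0.21 in the short term and -0.95 to -0.13 in the long term. It had -0.0077 in the short term with the hybridisation controls as a covariate. In the long term it had -0.092 with the scanner as a block and among the arrays of one scanner, with control 1 as the single control there.

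Of the lists, 2 passed in the short term with the strata block and 13 among the weak-control arrays, and 0 to 4 with 1 array left out. The weak-control arrays hold 1 short term knockdown, and one scanner 1 control beside the long term knockdowns; that lone array is assumed to vary like the other groups. In the long term the 9 became 0 with an estimated correlation, 0 with fry, 4 with the scanner block and 4 among the arrays of one scanner, of which 1 was among the 9; the others were microcephaly genes, up, and microglial and endothelial markers, down. Array weights passed 11 (5 of the 9), weights gene by gene 15 (7 of the 9), and leaving out 1 array 4 to 16 (4 to 8 of the 9), 16 being without knockdown 2 (5 of the 9). In the difference the 5 became 0 with an estimated correlation, with fry and with weights gene by gene, 2 with no filter and with the upper 40% (2 of the 5), 2 with the scanner block (0 of the 5: microcephaly genes, up, and endothelial markers, down), 3 with array weights (2 of the 5) and 1 to 11 with 1 array left out (1 to 5 of the 5). Between the controls the 16 became 0 with an estimated correlation, 9 with fry (8 of the 16), 9 without normalization (5 of the 16), 8 with the hybridisation covariate (8 of the 16) and 13 to 15 with 1 array left out.

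Reversed in the long term in camera's direction, with adjusted p under the scanner block and then among the arrays of one scanner, were DNA replication (0.806, 0.770), G2/M (0.552, 0.547), the respiratory chain (0.875, 0.865) and immediate-early genes (0.253, 0.253), the respiratory chain with its median still below 0 (-0.015), along with Rest (-0.058, -0.058) and Egr2 (-0.43, -0.43). Without knockdown 2 the ribosomal list (0.734), the respiratory chain (0.979) and Rps19 (0.00032) reversed, and with weights gene by gene oligodendrocyte precursors (0.798). With 1 array left out, adjusted p ran from 6.55e-10 to 0.734 for the ribosomal list and from 0.00136 to 0.979 for the respiratory chain. Short term Rest had -0.026 with the strata block and -0.12 among the weak-control arrays, and Rcor2 0.018 among the latter. In the difference, camera's direction for microglial markers turned with the scanner block (0.473) while their median stayed above 0 (0.12), and Rest had -0.30 with it, -0.14 with weights gene by gene, and -0.087, -0.15 and -0.017 without short term control 2, short term knockdown 1 and long term control 2 (range -0.15 to 0.36 with 1 array left out). Between the controls, no normalization turned camera's direction for the respiratory chain (0.239), microglial (0.290) and endothelial markers (0.148), with medians of 1.02, 2.56 and 1.83 above the 0.87 of all probe sets; Tpx2 (0.074) and Hdac1 (0.46) were above 0 but below it. Rest had -0.083 with probe sets averaged, -0.073 with the scanner block and without long term control 1 (-0.073 to 0.38 with 1 array left out), and -0.19 with the hybridisation covariate. The cause was not tested.

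Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated by 0.92, 0.90 and -0.42 in the short term and -0.13, -0.016 and 0.096 in the long term, and not every sample correlated best with its own number. The replicate block called 0 probe sets in the short term, the long term and the difference (1140, 112 and 304 at an unadjusted p below 0.05), and G2/M in the long term had an adjusted p of 0.0584 with it; it changed no other call. Signal over background was not given, so what dim probe sets could show is limited by the filter and the pseudocount.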

Other observations

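Between the controls of the time points, lists that did not pass as a whole held single genes that did. Among apical progenitor genes 1 was past the threshold, the receptor phosphatase gene Ptprz1, up by 1.55 (SE 0.25, adjusted p = 0.00977), with 4 higher and 5 lower adjusted over the list alone (list median -0.083, adjusted p = 0.322). The Wnt receptor gene Fzd5 rose by 1.59 (SE 0.31, adjusted p = 0.0219) and Wnt8b, a Wnt of the cortical hem, fell by 1.81 (SE 0.40, adjusted p = 0.0377) in the Notch and Wnt list (median -0.38, adjusted p = 0.188). Plk2 rose by 1.5 (SE 0.34, adjusted p = 0.0446) among p53 targets (median 0.014, adjusted p = 0.577), and Tarbp2, a partner of Dicer, by 1.45 (SE 0.26, adjusted p = 0.0148) among RNA interference genes (median 0.24, adjusted p = 0.333). Of the trithorax list (-0.12, 0.426) Kmt2c, a histone methyltransferase gene, had 0.998 (SE 0.23, adjusted p = 0.0425) and Wdr82 0.77 (SE 0.18, adjusted p = 0.0484). Stmn3 had 0.90 (SE 0.19, adjusted p = 0.0295) among postmitotic neuron genes (median 0.39, adjusted p = 0.251), Gria2 was the 1 synaptic gene past (list 0.61, 0.134) and Ogn, up by 2.06 (SE 0.29, adjusted p = 0.00417), the 1 meningeal gene (list 0.32, 0.322). The interferon (-0.13, 0.278) and Cajal-Retzius lists (-0.35, 0.275) held 0. With 1 array left out Ogn stayed past in 6 of 6 fits, Ptprz1 in 5 (0.0566 without long term control 1) and Tarbp2 in 3, those without short term control 1 or 2 or long term control 1 (adjusted p up to 0.0849). Fzd5 was past in 2, without short term control 2 or long term control 1 (up to 0.111), and Wnt8b and Plk2 in 1, without short term control 2 (up to 0.156 and 0.192). Kmt2c, Wdr82, Stmn3 and Gria2 were past in 0 of 6 (up to 0.176, 0.200, 0.147 and 0.171). These changes share the limit that time and batch coincide.

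The embryonic globin gene Hbb-y was lower by -2.47 in the long term controls (SE 0.52, adjusted p = 0.0332), a call kept in 1 of 6 fits with 1 array left out, that without short term control 3 (adjusted p up to 0.150). The erythroid list, too short for a test with 4 measured members, had mean log2 values of 9.44, 9.75 and 8.60 in the short term controls, 9.80, 9.47 and 9.02 in the short term knockdowns, 9.76, 9.15 and 9.29 in the long term controls and 10.27, 8.89 and 9.12 in the long term knockdowns.

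Across 12263 genes, which are not independent replicates, the short term and long term knockdown effects had a Pearson correlation of 0.334 (Spearman 0.298). With 1 array left out it ran from -0.051 (Spearman -0.063) without long term knockdown 2 to 0.419, with 0.0806 without long term control 3, and it was -0.0042 with the hybridisation controls as a covariate.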
